A study of Mus musculus with 6 samples.

How the data were processed

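RNA sequencing libraries from 6 brain samples of C57BL/6N mice at postnatal day 28 were analysed, 3 wild type and 3 with a homozygous Mettl5 knockout. Groups were taken from the genotype given in the labels and replicate numbers from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was captured on oligo(dT) beads and fragmented, and complementary DNA was made with random hexamer primers and amplified by PCR. Capture by poly(A) tail means that ribosomal RNA, and so its methylation, was not measured. The deposited values are FPKM, per the file headers, with 2 decimals and 1 column per sample. The submitters' processing notes name Bowtie2, RSEM and the mm10 genome build; versions, the annotation release, strand settings and filters are not given in the sources used here. RSEM divides fragments that match several genes by estimated probability, so genes with near-identical copies carry uncertain values.

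The deposited table held 18491 genes, of which 18490 listed only curated protein-coding RefSeq transcripts. It held no mitochondrially encoded gene and no Xist, so those were not analysed here. For 28 genes the symbol was a spreadsheet date number or a dash, and these were filled by gene ID. Of the gene IDs, 18450 were found in the RefSeq gene table of GRCm38, the assembly that mm10 names, which gave the coordinates. Whole reads could not be recovered from FPKM values of multi-transcript genes with 2 decimals, so no count model was run. Steps between the smallest values of 21 to 34 lowly expressed single-transcript genes gave relative depths of 0.999 to 1.0, but rounding to 2 decimals pulls such ratios toward 1, so small differences in depth are not excluded. Absolute depth remained unknown, so no counting interval or floor is given.

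The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend and robust prior) on log2(FPKM + 1) in genes with a mean of at least 1 FPKM over the 6 samples, 12885 in all. It was 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 45 lists that had at least 5 tested members, and again with an estimated correlation and with fry. Of 48 lists, the mitochondrially encoded list and the pituitary list had no tested member, and 1 list of 6 sex-linked genes served as a check. A list's level in a library is the median over its members of log2(FPKM + 1) minus the gene's wild-type mean. Exact permutation tests used SciPy 1.17.1, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for tables and figures.

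The test, filter, pseudocount, gene lists, alternatives and naming rule were fixed before the data were examined. Named genes were Mettl5, then the 12 genes of largest change in each direction among those that passed without overlap. As fewer than 5 passed in each direction, up to 5 with the lowest unadjusted p in each direction were named instead, leaving out symbols of predicted genes. Up to 4 tested members with the lowest unadjusted p were named from each list described, and the sex-linked genes were added. Genes named outside this rule are said to have been chosen after their values were seen.

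On simulated values with the real genes' means and spreads and 50 genes changed at each size, the same steps called 28% of genes changed by 0.5 on the log2 scale, 66% at 1, 96% at 2 and 100% at 3 among 12885 genes. Of the genes left unchanged, 3 were called. All these changes were simulated together. The adjustment is stricter where fewer genes change, so these rates overstate how often a lone changed gene would be called. Noise was drawn independently for each gene and library, without the correlation between genes or between libraries. The rates may therefore not transfer to these libraries. A simulated shift of -0.5 in the oligodendrocyte and myelin list, with genes otherwise independent, gave a camera adjusted p of 3.73e-07 and 0 other lists. The same shift was missed when the correlation was estimated (adjusted p = 0.247 with an estimated correlation). The real list had an estimated correlation of 0.79, which the simulation did not carry, so its result does not transfer to that list.

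The titles give both genotypes the numbers 1 to 3, without saying what they mark. Deviations from the group means correlated between same-numbered libraries across genes (0.485, 0.413 and 0.539 for pairs 1, 2 and 3), and all other wild-type and knockout combinations were negative (-0.326 to -0.103). Centring each genotype on its own mean makes the other combinations negative on balance once the same-numbered ones are positive, so they add no evidence. Every pair exceeded 0.1, so the numbers were taken to pair the samples, on evidence from the data rather than the labels. Few other matchings of 3 libraries to 3 exist, so chance could give this matching. A fit with the replicate number as a block was run as an alternative, along with other pseudocounts, filters, scalings, sample weights and the omission of each library in turn. Spearman correlations between libraries across the tested genes were 0.966 to 0.993; genes are not independent replicates.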

Results

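Messenger RNA from the brains of C57BL/6N mice, an inbred laboratory strain, was measured by RNA sequencing at postnatal day 28. The 6 samples formed 2 groups, 3 wild-type and 3 Mettl5 knockout. Mettl5 encodes a methyltransferase that places N6-methyladenosine on the small-subunit ribosomal RNA. Each library is named here by its genotype and replicate number. Expression was given for 18491 genes as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library), and per-library sums ran from 350727 to 377334. Absolute depth is unknown, because FPKM values hold no read totals. Between 16615 and 16794 genes had a value above 0 in a library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 6 libraries. Ddx3y averaged 13.6 ± 1.1 FPKM in the wild type and 13.9 ± 0.33 FPKM in the knockout (SD, n = 3 each).

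The first comparison asked how far the Mettl5 transcript itself differed between the genotypes. Mettl5 (gene ID 75422; chromosome 2, 69871195 to 69886634, GRCm38) was lower in all 3 knockout libraries, but it was still present. Wild-type libraries 1, 2 and 3 held 4.78, 5.16 and 5.92 FPKM. Knockout libraries 1, 2 and 3 held 2.79, 3.81 and 2.40 FPKM. The means were 5.29 ± 0.58 and 3.0 ± 0.73 FPKM (SD, n = 3 each), so the knockout mean was 0.567 of the wild-type mean. The log2 fold change on the log2(FPKM + 1) scale was -0.66 (SE 0.15; 95% confidence interval -1.02 to -0.31). This scale understates the change of low genes. The limma p-value was 0.00266 before adjustment and 0.79 after Benjamini-Hochberg adjustment over 12885 genes. A 2-sided exact permutation of the 3 against 3 FPKM values gave p = 0.1, the smallest p this design allows. The part of the gene removed in the knockout is not given in the sources used here, and a gene-level FPKM does not show which exons the remaining fragments came from.

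**Figure D1:**
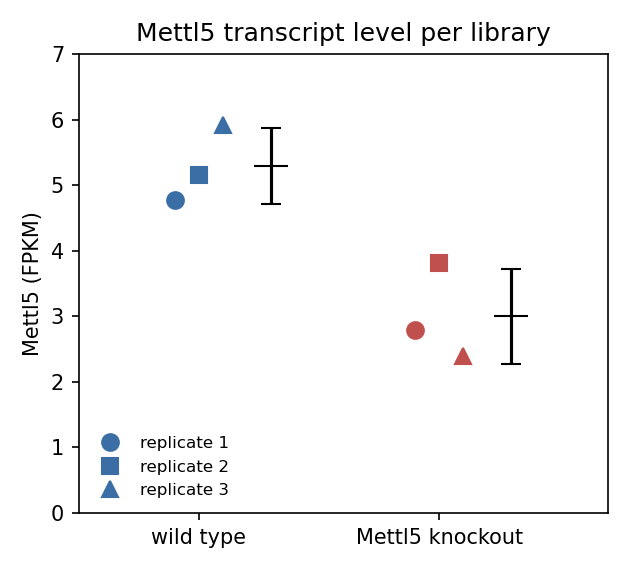
Mettl5 level in FPKM (vertical axis) for each of the 3 wild-type and 3 knockout libraries, with marker shape giving the replicate number and the black bars the group mean with its SD. All 3 knockout libraries, at 2.40 to 3.81 FPKM, sit below the wild-type range of 4.78 to 5.92 FPKM.

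The second comparison asked which single genes differed between the knockout and wild-type brains. Among the genes with the lowest unadjusted p, those on the lower side were Rpa3, S100a13, Trim59, Bfsp2 and Hspb1. Those on the higher side included Cnn2, Mustn1, Cort and Rad9b. None of these genes passed the threshold, and their values are given for description only. Rpa3, a subunit of the single-stranded DNA-binding replication protein A, had 6.99 ± 0.60 FPKM in the wild type and 4.16 ± 0.38 FPKM in the knockout (SD, n = 3 each). Its log2 fold change was -0.63 (SE 0.11). The calcium-binding protein gene S100a13 had 19.4 ± 2.1 and 12.7 ± 0.73 FPKM, and Trim59 had 7.83 ± 0.75 and 4.01 ± 0.93 FPKM. Bfsp2, a beaded filament gene, had 3.82 ± 0.97 and 1.52 ± 0.30 FPKM. On the higher side, Cnn2, an actin-binding calponin gene, had 3.92 ± 0.25 FPKM in the wild type and 6.13 ± 0.61 FPKM in the knockout. The neuropeptide gene Cort had 4.69 ± 0.79 and 7.26 ± 0.32 FPKM. Mustn1 and Rad9b were low in both groups, with knockout means of 2.04 ± 0.28 and 2.53 ± 0.39 FPKM against 0.923 ± 0.18 and 1.36 ± 0.18 FPKM.

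Of the 12885 genes tested, 0 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, and the lowest adjusted p was 0.79. At an unadjusted p under 0.05 there were 780 genes, 305 higher and 475 lower in the knockout. With values rescaled to a common sum per library, that split was 429 higher and 378 lower, and without knockout library 3 it was 334 and 333. Without wild-type library 2 the count at an unadjusted p under 0.05 was 315, and with array weights it was 1361. The 3 values of one genotype lay entirely above the 3 of the other for 706 genes that were higher and 828 that were lower, together 11.9% of the genes tested. Chance gives 10% for exchangeable libraries, a condition that libraries paired by replicate number do not meet, so this share here and in the lists is no measure of chance. With the replicate number as a block, limma again called 0 genes (lowest adjusted p 0.285), and 1842 genes had an unadjusted p under 0.05. Without wild-type library 3 the count was 1, from Rps27rt, a gene chosen here after its values were seen. Rps27rt was listed at 32.31, 15.80 and 0 FPKM in the wild type and at 0 in all 3 knockouts, and as a retrotransposed copy of Rps27 it can share reads with that gene. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

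The third comparison asked whether genes of known groups moved together in the knockout. Of 45 gene lists tested with limma's camera at a preset inter-gene correlation of 0.01, 16 passed a Benjamini-Hochberg adjusted p of 0.05, 13 lower and 3 higher in the knockout. The lists of lower expression covered myelin, cholesterol synthesis, chaperones, mitochondrial proteins, glia, choroid plexus, neurons in general, and thalamic and monoaminergic neurons. The lists of higher expression were cerebellar neuron markers, glutamate receptors with their postsynaptic scaffold, and glucocorticoid response genes. No list passed when the correlation was estimated from the data, and the adjusted p of the 16 lists then lay between 0.775 and 0.825. The directional test fry also called 0 lists (lowest adjusted p 0.569). With the replicate block, camera called 19 lists and none with an estimated correlation (lowest adjusted p 0.705). In a 2-sided exact permutation of the list medians per library, 5 of the 16 lists separated the genotypes fully (p = 0.1, the smallest possible): myelin, precursor, heat shock, choroid plexus and pan-neuronal genes. In the other 11 the genotypes overlapped, but the permutation ignores the pairing by replicate number. In 5 of these 11 the knockout differed in the same direction within all 3 pairs: cholesterol synthesis, oxidative phosphorylation, mitochondrial ribosomal, monoaminergic and glutamate receptor genes. Among the lists not called, only the presynaptic genes also reached p = 0.1 in the exact permutation. The 16 lists were called on these same data, so separation among them is no independent support. Over all genes tested, 0 members of any list passed singly in limma. The members with an unadjusted p under 0.05 are counted beside each of the 16 called lists.

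**Figure D2:**
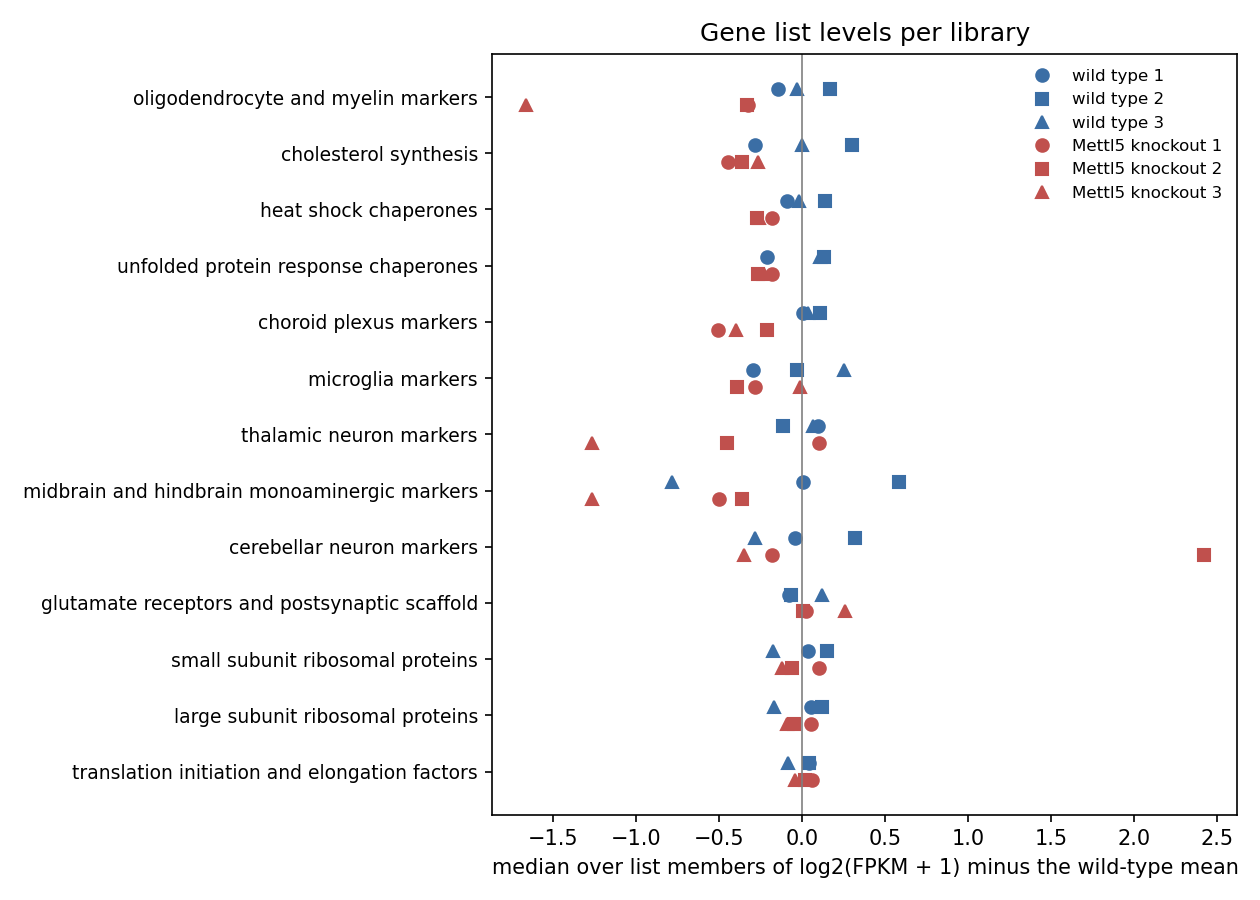
Level of 13 gene lists in each library, as the median over list members of log2(FPKM + 1) minus each gene's wild-type mean (horizontal axis), with 1 point per library, colour giving the genotype and marker shape the replicate number. Knockout library 3 sits at -1.66 in the oligodendrocyte and myelin list, and knockout library 2 at 2.42 in the cerebellar list.

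Oligodendrocyte and myelin markers were lower in the knockout as a group, with a median log2 fold change of -0.73 and all 22 members lower. The gene of myelin basic protein, Mbp, chosen after its values were seen, had 4087 ± 471 FPKM in the wild type and 2528 ± 1146 FPKM in the knockout (SD, n = 3 each). The lineage transcription factors Sox10 (33.3 ± 2.7 and 22.5 ± 4.6 FPKM) and Olig1 (105 ± 12 and 71.8 ± 16 FPKM) were also separated by genotype. Ermn, a myelinating oligodendrocyte gene, had 31.3 ± 8.6 and 13.7 ± 5.6 FPKM, and Enpp2 had 139 ± 25 and 92.6 ± 13 FPKM. The camera adjusted p was 3.84e-13. It was not kept when gene correlation was taken from the data (adjusted p = 0.775 with an estimated correlation). The unadjusted camera p at the preset correlation was 8.54e-15. Grouping wild-type library 1 with knockout libraries 2 and 3 against the rest gave this list a lower one, 1.63e-15, so its size is no measure of a genotype effect. Of the 22 members, 16 had no overlap between the genotypes, against 11.9% of all genes tested. Members moved together (estimated correlation 0.79), so this share is no measure of chance. At an unadjusted p under 0.05 there were 7 members, while 0 passed over all genes, and 0 passed when adjusted over the list alone. The list medians of knockout libraries 1, 2 and 3 were -0.32, -0.33 and -1.66, against -0.15, 0.17 and -0.03 in wild-type libraries 1, 2 and 3. Without knockout library 3 the median log2 fold change was -0.34, and the thalamic neuron markers of that library, at a median of -1.27, were low as well.

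Oligodendrocyte precursor markers had a median log2 fold change of -0.24, with 10 of 13 members lower. Gpr17, a receptor of differentiating precursors, had 28.6 ± 6.1 FPKM in the wild type and 16.9 ± 1.1 FPKM in the knockout (SD, n = 3 each) and was the 1 member that passed when adjusted over the list alone. Bcas1 (97.7 ± 34 and 48.9 ± 19 FPKM) and Neu4 (4.71 ± 0.05 and 3.63 ± 0.26 FPKM) were lower. In this list 6 members had an unadjusted p under 0.05, 5 lower and 1 higher, and 0 passed over all genes. The camera adjusted p was 0.00945 (adjusted p = 0.775 with an estimated correlation), and without wild-type library 3 the call was lost (median -0.26, adjusted p 0.14).

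Cholesterol synthesis genes were lower in the knockout as a group, with all 23 members lower and a median log2 fold change of -0.32. Farnesyl diphosphate synthase, Fdps, had 41.8 ± 8.9 FPKM in the wild type and 27.3 ± 2.4 FPKM in the knockout (SD, n = 3 each). Nsdhl had 17.0 ± 3.4 and 11.6 ± 0.55 FPKM, and Idi1 had 24.2 ± 7.3 and 13.9 ± 1.6 FPKM. Insig1, which restrains sterol synthesis, had 28.6 ± 5.5 and 20.7 ± 2.1 FPKM. The camera adjusted p was 9.85e-13 (adjusted p = 0.775 with an estimated correlation). In 11 of the 23 genes the genotypes did not overlap, against 11.9% of all genes tested. These genes also moved together (estimated correlation 0.77), so this share is no measure of chance. At an unadjusted p under 0.05 there were 11 genes, while 0 genes passed over all genes, and 0 passed when adjusted over the list alone. All 23 genes were highest in wild-type library 2, and without that library the median log2 fold change was -0.19.

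Chaperones of the cytosol and of the endoplasmic reticulum were lower in the knockout in 2 separate lists. All 17 heat shock chaperones were lower, with a median log2 fold change of -0.21. The small heat shock protein gene Hspb1 had 10.6 ± 1.0 FPKM in the wild type and 7.09 ± 0.68 FPKM in the knockout (SD, n = 3 each), and was the 1 member that passed when adjusted over the list alone. The constitutive chaperone Hspa8 had 1266 ± 143 and 1006 ± 64 FPKM, and Cryab, a small heat shock protein also found in oligodendrocytes, had 130 ± 57 and 63.3 ± 15 FPKM. The heat shock list had a camera adjusted p of 6.6e-07 (adjusted p = 0.775 with an estimated correlation). Of the unfolded protein response chaperones, 19 of 21 were lower, with a median log2 fold change of -0.19. Manf, a secreted stress protein of the endoplasmic reticulum, had 17.9 ± 2.8 and 12 ± 1.0 FPKM. The disulfide isomerase genes Pdia4 (15.6 ± 3.2 and 10.5 ± 0.056 FPKM) and Pdia6 (42.1 ± 6.5 and 31.6 ± 3.2 FPKM) and the gene Sdf2l1 (6.18 ± 2.2 and 2.96 ± 0.26 FPKM) had no overlap between genotypes. That list had a camera adjusted p of 1.05e-06 (adjusted p = 0.775 with an estimated correlation), and 0 of its members passed when adjusted over the list alone. At an unadjusted p under 0.05 there were 5 heat shock and 6 unfolded protein response genes, and 0 members of either list passed over all genes. The unfolded protein response level of wild-type library 1 (-0.21) lay within the knockout range (-0.27 to -0.18), and the difference rested on wild-type libraries 2 and 3 (0.13 and 0.11). Without wild-type library 1 the median log2 fold change was -0.29.

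Choroid plexus, microglial and astrocyte markers were lower in the knockout as groups. All 11 choroid plexus markers were lower, with a median log2 fold change of -0.33. Calml4 had 1.45 ± 0.36 FPKM in the wild type and 0.647 ± 0.22 FPKM in the knockout, and the folate receptor gene Folr1 had 2.61 ± 0.72 and 1.73 ± 0.30 FPKM (SD, n = 3 each). The camera adjusted p was 2.25e-05 (adjusted p = 0.775 with an estimated correlation), and with a pseudocount of 0.1 the median was -0.51. Enpp2, the choroid plexus marker with the lowest p, also belongs to the oligodendrocyte list. All 16 microglial markers were lower, with a median log2 fold change of -0.24. The complement gene C1qa had 36.2 ± 2.0 and 31.7 ± 1.2 FPKM. The microglial list had a camera adjusted p of 0.000269 (adjusted p = 0.825 with an estimated correlation). Its median was -0.41 without wild-type library 1. The call was lost without wild-type library 3 (median -0.095, adjusted p 0.152) and without knockout library 2 (median -0.13, adjusted p 0.0579). Of 15 astrocyte markers, 11 were lower, with a median log2 fold change of -0.074 and a camera adjusted p of 0.0434 (adjusted p = 0.825 with an estimated correlation). Gfap, the intermediate filament gene of astrocytes, had 79.7 ± 10 and 53.1 ± 7.6 FPKM and was the 1 astrocyte marker that passed when adjusted over the list alone. The gap junction gene Gja1 had 74.2 ± 2.6 and 62.9 ± 4.6 FPKM. The astrocyte median was -0.25 without knockout library 2, -0.15 with array weights, -0.046 with rescaling to a common sum and -0.040 with quantile normalization. The astrocyte call was lost without wild-type library 3 (median -0.13, adjusted p 0.152), without knockout library 1 (-0.025, 0.506) and without knockout library 3 (-0.063, 0.275). No choroid plexus or microglial marker passed when adjusted over its list alone, and 0 members of these 3 lists passed over all genes. At an unadjusted p under 0.05 there were 4 choroid plexus, 0 microglial and 3 astrocyte markers.

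Nuclear genes for mitochondrial proteins were lower in the knockout by small amounts. Of 76 oxidative phosphorylation genes, 70 were lower, with a median log2 fold change of -0.11. Uqcr10, a complex III subunit gene, had 151 ± 17 FPKM in the wild type and 122 ± 11 FPKM in the knockout (SD, n = 3 each). The list had a camera adjusted p of 3.3e-06 (adjusted p = 0.825 with an estimated correlation). Its median was -0.032 without wild-type library 2, -0.18 without wild-type library 3 and -0.16 without knockout library 2, and the call was lost without knockout library 3 (median -0.043, adjusted p 0.0605). Of 76 mitochondrial ribosomal protein genes, 59 were lower, with a median log2 fold change of -0.065. Mrpl34 had 25.0 ± 2.3 and 18.6 ± 1.1 FPKM, and Mrps6 had 26.3 ± 3.8 and 18.8 ± 2.2 FPKM. That list had a camera adjusted p of 0.000835 (adjusted p = 0.825 with an estimated correlation). The median was -0.12 without wild-type library 3, -0.099 without knockout library 1 and -0.038 with rescaling to a common sum. The call was lost without wild-type library 2 (-0.032, adjusted p 0.185) and without knockout library 3 (-0.024, adjusted p 0.127). In the first list 1 gene and in the second 4 genes had an unadjusted p under 0.05, and in both 0 passed over all genes and 0 when adjusted over the list alone.

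The cytosolic ribosome, whose small-subunit RNA Mettl5 methylates, differed little in the transcripts of its proteins. Small-subunit ribosomal protein genes had a median log2 fold change of -0.030 over 32 genes (camera adjusted p 0.476). Large-subunit genes had a median of -0.045 over 47 genes (camera adjusted p 0.472). Rps24 had 335 ± 23 FPKM in the wild type and 302 ± 22 FPKM in the knockout, and Rps2 had 334 ± 9.3 and 369 ± 27 FPKM (SD, n = 3 each). Rpl35a had 180 ± 20 and 156 ± 20 FPKM. Without wild-type library 3 both lists were called lower, with medians of -0.12 each and adjusted p of 0.000212 and 5.35e-05. Without knockout library 1 they were also called lower (-0.081 and -0.071, adjusted p 0.0186 and 0.0227), while without wild-type library 2 the medians were 0.043 and 0.017 (adjusted p 0.169 and 0.226). Ribosome biogenesis factors (median 0.017 over 70 genes, adjusted p 0.472) and translation initiation and elongation factors (0.013 over 53 genes, adjusted p 0.492) were not called. Eef2k, the kinase of elongation factor 2, had 6.78 ± 0.98 and 9.21 ± 0.85 FPKM. Genes of the ribosomal and messenger RNA methylation machinery were not called either (median -0.011 over 29 genes, adjusted p 0.996). Among them, Mettl16 had 7.62 ± 1.7 and 5.11 ± 0.22 FPKM, and Mettl3 had 9.93 ± 0.70 and 8.08 ± 0.67 FPKM. Trmt112, the cofactor of Mettl5, was chosen after its values were seen and had 32.7 ± 3.0 and 31.1 ± 3.8 FPKM. In these 5 lists, 0 genes passed over all genes and 0 when adjusted over the list alone.

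Neuronal markers moved in both directions. Of 15 pan-neuronal markers, 13 were lower in the knockout, with a median log2 fold change of -0.11. The neurofilament genes Nefm (101 ± 23 FPKM in the wild type and 56.9 ± 12 FPKM in the knockout; SD, n = 3 each) and Nefl (174 ± 28 and 124 ± 4.1 FPKM) were the 2 that passed when adjusted over the list alone. Rbfox3, which encodes the nuclear antigen NeuN, had 83.5 ± 6.0 and 105 ± 15 FPKM and was higher. The pan-neuronal list had a camera adjusted p of 0.00945 (adjusted p = 0.775 with an estimated correlation). Its median was -0.18 without knockout library 3 and -0.075 with quantile normalization, and the call was lost without knockout library 2 (-0.090, adjusted p 0.0579). Glutamate receptor and postsynaptic scaffold genes were higher, 36 of 44, with a median log2 fold change of 0.11. Camk2b had 204 ± 10 and 233 ± 11 FPKM, and the receptor gene Gria1 had 88.0 ± 11 and 104 ± 10 FPKM. That list had a camera adjusted p of 0.00612 (adjusted p = 0.825 with an estimated correlation). The call was lost without wild-type library 1 (median 0.096, adjusted p 0.21), wild-type library 2 (0.080, 0.0709) or knockout library 3 (0.0086, 0.845), and with array weights (0.059, 0.147). Cortical excitatory neuron markers (median 0.15 over 18 genes) were not called (camera adjusted p 0.0998) and were called higher with the replicate block (adjusted p 0.0114, and adjusted p = 0.705 with an estimated correlation). They were also called higher without wild-type library 3 (0.28, adjusted p 0.00607), without knockout library 2 (0.31, 0.000423), with array weights (0.16, 0.0372) and with a filter at a mean of 5 FPKM (0.16, 0.0212). Neurod2 had 33.0 ± 4.1 and 45.6 ± 4.2 FPKM. No glutamate receptor, scaffold or cortical gene passed when adjusted over its list alone, and 0 genes of the 3 lists passed over all genes. At an unadjusted p under 0.05 there were 3 pan-neuronal genes (2 lower, 1 higher) and 0 glutamate receptor or scaffold genes. There were 3 cortical genes (1 lower, 2 higher), the lower one being Lamp5.

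Thalamic neuron markers were lower in the knockout, 12 of 13, with a median log2 fold change of -0.51 and a camera adjusted p of 0.000835 (adjusted p = 0.825 with an estimated correlation). The list medians of knockout libraries 1, 2 and 3 were 0.10, -0.46 and -1.27, and 12 of 13 markers were lowest in knockout library 3. Rgs16 had 8.85 ± 1.0 FPKM in the wild type and 5.67 ± 2.2 FPKM in the knockout, and Tnnt1 had 8.84 ± 1.5 and 4.39 ± 4.2 FPKM (SD, n = 3 each). Without knockout library 3 the median was -0.13 and the call was lost (adjusted p 0.315), as it was with array weights (-0.14, 0.347), and without knockout library 1 the median was -0.85. All 9 members of the midbrain and hindbrain monoaminergic list were lower, with a median of -0.82 and a camera adjusted p of 0.00135 (adjusted p = 0.825 with an estimated correlation). Among them, Slc5a7 is a choline transporter gene, so the list is not purely monoaminergic. The list medians were 0.006, 0.59 and -0.79 in wild-type libraries 1, 2 and 3. In knockout libraries 1, 2 and 3 they were -0.50, -0.36 and -1.27. Of the 9 markers, 7 were highest in wild-type library 2 and 6 lowest in knockout library 3. Tyrosine hydroxylase, Th, was 8.41, 9.37 and 7.44 FPKM in wild-type libraries 1, 2 and 3 and 6.94, 6.03 and 0.45 FPKM in knockout libraries 1, 2 and 3. The vesicular transporter gene Slc18a2 had 7.22 ± 1.6 and 3.8 ± 1.6 FPKM. Without knockout library 3 the monoaminergic median was -0.41, and with a pseudocount of 0.1 it was -1.36. Each of the 2 lists had 1 member with an unadjusted p under 0.05, while 0 passed over all genes and 0 when adjusted over the list alone.

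Cerebellar neuron markers were higher in the knockout, 16 of 18, with a median log2 fold change of 0.70 and a camera adjusted p of 0.00612 (adjusted p = 0.825 with an estimated correlation). All 18 were highest in knockout library 2. Neurod1, a granule neuron transcription factor gene, was 61.38 FPKM in that library and 8.28 to 11.45 FPKM in the other 5. The Purkinje cell gene Pcp2 and the granule cell receptor gene Gabra6, chosen after their values were seen, reached 273.73 and 86.25 FPKM there and at most 13.35 and 4.77 FPKM in the other 5. Without knockout library 2 the list median was -0.35, and the list was no longer called (adjusted p 0.349). The call was also lost without wild-type library 3 (0.51, adjusted p 0.0633) and with array weights (0.36, adjusted p 0.34), and the median was 1.26 without knockout library 3. At an unadjusted p under 0.05 there were 0 members; 0 passed over all genes and 0 when adjusted over the list alone.

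**Figure D3:**
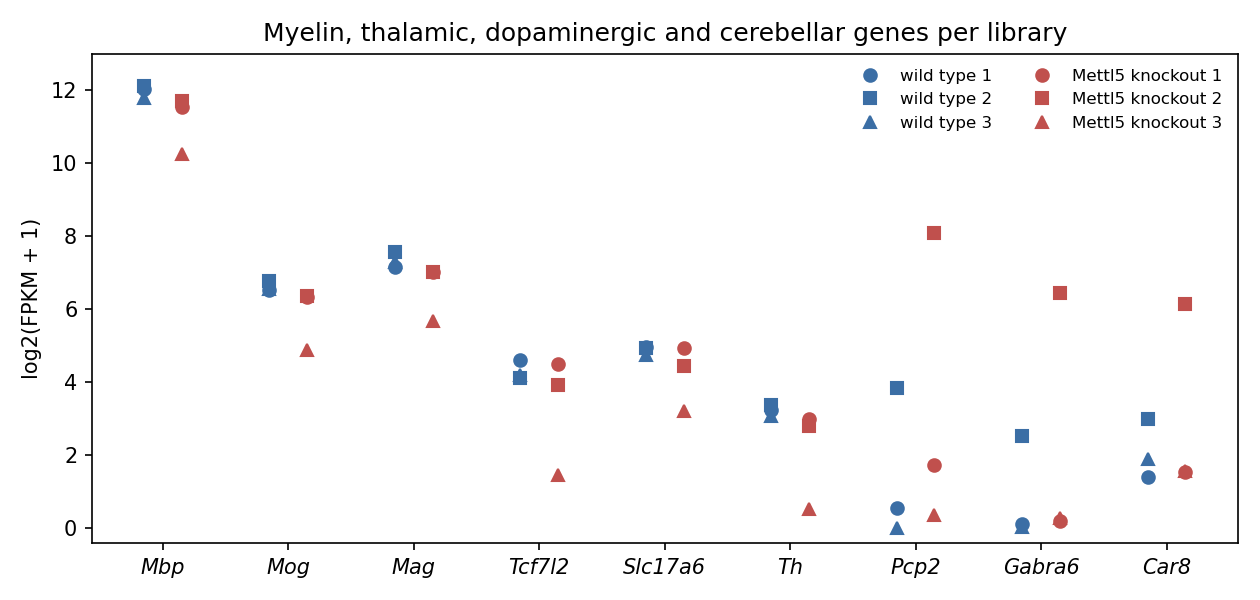
Level of 9 genes of myelin (Mbp, Mog, Mag), thalamus (Tcf7l2, Slc17a6), dopaminergic neurons (Th) and cerebellum (Pcp2, Gabra6, Car8) in each library, as log2(FPKM + 1) on the vertical axis, with 1 point per library. The 9 genes were chosen after their values were seen. Knockout library 3 is lowest in the myelin, thalamic and dopaminergic genes (Mbp 1220 FPKM against 3002 or more elsewhere), and knockout library 2 is highest in the cerebellar genes.

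Glucocorticoid response genes were higher in the knockout, 14 of 18, with a median log2 fold change of 0.23 and a camera adjusted p of 0.0177 (adjusted p = 0.825 with an estimated correlation). Klf9 had 60.6 ± 4.4 FPKM in the wild type and 71.8 ± 8.3 FPKM in the knockout, and the co-chaperone gene Fkbp5 had 20.8 ± 9.6 and 26.8 ± 4.0 FPKM (SD, n = 3 each). The call was kept without wild-type library 1 and without knockout library 3 (median 0.51). It was lost without wild-type library 2 (0.18, adjusted p 0.0709), wild-type library 3 (0.076, 0.221), knockout library 1 (0.17, 0.189) or knockout library 2 (0.0057, 0.403). Of its members 0 had an unadjusted p under 0.05, 0 passed over all genes and 0 when adjusted over the list alone.

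The remaining lists were not called. Hypothalamic neuropeptide markers (9 of 9 lower, median -0.39, camera adjusted p 0.186) and blood markers (8 of 8 lower, median -0.91, camera adjusted p 0.22) were called lower with the replicate block (adjusted p 0.0204 and 0.00193). Both of these calls were lost with the estimated correlation (adjusted p = 0.717 with an estimated correlation for the first, and adjusted p = 0.705 with an estimated correlation for the second). The hypothalamic list was also called lower without wild-type library 3 (-1.09, adjusted p 0.00112), without knockout library 1 (-0.82, 0.0115) and with no filter (-0.28, 0.0361). The blood list was also called lower without wild-type library 1 (-2.09, adjusted p 0.0244) and with array weights (-2.17, 0.0103). The hemoglobin gene Hbb-bs ranged from 2.91 FPKM in knockout library 1 to 957.61 FPKM in wild-type library 2. Integrated stress response targets of ATF4 (median 0.012 over 32 genes, adjusted p 0.637) and p53 targets (0.047 over 16 genes, adjusted p 0.492) were not called. In the first of these Psat1 had 60.0 ± 7.1 FPKM in the wild type and 46.2 ± 6.2 FPKM in the knockout, and Cebpb had 3.92 ± 0.23 and 5.12 ± 0.32 FPKM (SD, n = 3 each). Microcephaly genes (median -0.018 over 15 genes) and proliferation genes (-0.0074 over 16 genes) each had an adjusted p of 0.996, and the latter were called lower with no filter (-0.058, adjusted p 0.0127), as were pituitary markers, of which none reached the filter (-0.16, 0.0115). Genes near Mettl5 on chromosome 2 had a median of 0.058 over 18 genes (adjusted p 0.472), and the neighbour Phospho2 had 14.8 ± 1.0 and 12.2 ± 0.32 FPKM. Interferon response genes had a median of 0.11 over 29 genes (adjusted p 0.492). That list was called higher without wild-type library 3 (0.47, adjusted p 3.48e-16) and lower without wild-type library 2 (-0.26, adjusted p 0.0345). Immediate early genes (median -0.057 over 25 genes, adjusted p 0.476) were called lower without knockout library 1 (-0.24, adjusted p 0.00841), and Arc had 66.9 ± 10 and 38.8 ± 16 FPKM. Without wild-type library 3, presynaptic genes (0.097, adjusted p 0.0418) and voltage-gated ion channels (0.13, 0.0418) were called higher, as were striatal markers without wild-type library 2 (0.44, 1.89e-05). Ependymal markers were called lower without wild-type library 1 (-0.34, adjusted p 0.0405). The 29 lists not called had adjusted p-values between 0.0998 and 0.996. The median, the mean and the direction of the test differed in sign for GABA receptors, endothelial markers, striatal markers, olfactory markers and the methylation machinery.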

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

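The settings that leave out knockout libraries 2 and 3 together or a whole pair, and those that join the block to another change, were chosen after the data were seen. Leaving out knockout libraries 2 and 3 leaves 1 knockout library, which is assumed to vary like the wild type, the only source of spread there. Mettl5 kept its direction in all 21 alternatives (log2 fold change -0.82 to -0.48, and -0.80 to -0.55 with 1 library left out), with an adjusted p of 0.283 to 1.0. The count of genes past the threshold was 0 in 18 of 21 alternatives and 0 to 1 with 1 library left out; the lowest adjusted p ranged from 0.00227 to 1.0. It was 1 with no filter (Hist2h2aa2, listed at 1.61, 1.58 and 1.61 FPKM in the wild type and 0 in the knockouts; its paralog Hist2h2aa1 held 10.1 to 14.6 FPKM). It was also 1 without wild-type library 3 (Rps27rt) and with the replicate block without pair 3 (Hbb-bs). These 3 genes were singled out after their values were seen, and the cause was not tested.

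The count of lists was 11 to 18 with 1 library left out, against 16. It was 0 with camera at an estimated correlation and 0 with fry, and 0 for both with the replicate block. With the preset correlation, 6 of the 16 lists kept their call in every setting that could test them: myelin, cholesterol synthesis, both chaperone lists, choroid plexus and monoaminergic markers. The replicate block added 3 calls, and it changed no other. Reversals were the cerebellar list without knockout library 2 (-0.35; 1.26 without knockout library 3), without knockout libraries 2 and 3 (0.028) and with the block without pair 2 (0.0057); thalamic markers without knockout libraries 2 and 3 (0.10); and glucocorticoid genes with the block without pair 2 (0.035). Lists with no call in all 6 libraries that were called in the opposite direction were small-subunit ribosomal proteins with the block without pair 2 (0.052), immediate early genes without knockout libraries 2 and 3 (0.32) and interferon genes without wild-type library 2 (-0.263; 0.467 without wild-type library 3). Some of these values are medians whose sign differs from that of the test. Among all list values, 44 gained and 28 lost a call in the same direction, and 1 of the named genes' values gained one; the causes were not tested. edgeR and DESeq2 were not run, since no counts could be recovered. With absolute depth unknown, how far counting noise limits low genes could not be set.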

Other observations

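The tests of tissue content, of 1 high library, of within-pair differences and of the sample splits, the block without pair 2, and the use of other values to weigh explanations were chosen only after the result was seen, whereas the estimated correlation, the replicate block and the omission of single libraries were planned.

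Interferon response genes stood out in wild-type library 3, where 24 of 29 tested members were highest. The list median there was 0.84, against -0.37 and -0.47 in wild-type libraries 1 and 2 and -0.19 to 0.16 in the knockouts. Irf7 was 16.67 FPKM in that library and at most 7.46 FPKM elsewhere, and Ifit3 was 21.93 FPKM against at most 11.04 FPKM. The hypothalamic peptide genes Pmch and Hcrt were 1.23 and 0.24 FPKM in wild-type library 3 and 0.07 and 0 FPKM in knockout library 3. In the other 4 libraries they were 16.92 to 64.90 and 5.25 to 13.05 FPKM. The serotonin transporter gene Slc6a4 was 4.71 FPKM in wild-type library 2 and at most 1.03 FPKM elsewhere. The striatal gene Ppp1r1b was 197.9 and 224.7 FPKM in wild-type and knockout libraries 2 and 45.51 to 114.3 FPKM in the other 4. All of these genes were chosen after their values were seen.

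Myelin markers were lower in all 3 knockout libraries, most of all in knockout library 3. Regional content is a candidate explanation, as the thalamus is rich in myelinated fibres. Thalamic markers were at -1.27 in knockout library 3 and -0.46 in knockout library 2. Both lay below the lowest wild-type library (-0.12) by more than the wild-type SD of 0.11. Less thalamic tissue may therefore account for part of the difference in those 2 libraries. Knockout library 2 is the weaker case: its mean over thalamic members was -0.27, and of 13 markers 1 was lowest and 2 were highest there. Less thalamic tissue is argued against for knockout library 1, where thalamic markers were at 0.10, above the wild-type mean, while myelin was at -0.32 (-0.18 against wild-type library 1, about the wild-type SD of 0.16). Less tissue of other regions was not decided there. Monoaminergic markers were at -0.50, within the wild-type range of -0.79 to 0.59. Against wild-type library 1 they were at -0.51, within the wild-type SD of 0.69, so a loss of such tissue was not decided. Wild-type library 3 was lower in them (-0.79), with myelin at -0.03. An effect of the genotype stays open (adjusted p = 0.775 with an estimated correlation), and 2 of the 3 knockouts also differ in thalamic markers.

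Cerebellar markers were higher in the knockout group. An effect of the size of the list value (0.70) in all 3 knockouts is only weakly argued against. The median member differed between knockout and wild type by 0.036 in pair 1 and -0.038 in pair 3 (SD over members 0.36 and 0.42). Members moved together (estimated correlation 0.94), so that SD does not measure the spread between libraries. The wild-type SD of the list was 0.30, and these pairs are few. A smaller effect of the genotype stays open: without knockout library 2 the list was not called and its median was -0.35, but that includes the high wild-type library 2 (0.32), and with the replicate block without pair 2 it was 0.0057. Cerebellar tissue in knockout library 2 may account for the call, as 18 of 18 markers were highest there, from both Purkinje and granule cells. Of these markers, Gabra6, Pvalb, Neurod1, Calb1 and Eomes are also in other lists.

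Cholesterol synthesis genes were lower in the knockout group, and 3 explanations could not be decided between. A single high wild-type library is one, as all 23 genes were highest in wild-type library 2. Without it camera still called the list (median -0.19), as it did with the replicate block without pair 2 (-0.18), and the list was lower in the knockout within pairs 1, 2 and 3 (-0.16, -0.66 and -0.27), but 2 pairs are few and across pairs the level of wild-type library 1 (-0.29) lay below that of knockout library 3 (-0.27). Lower oligodendrocyte content is another, but knockout library 3, lowest in myelin, lay 0.14 above the mean of the other 2 knockouts, within the wild-type SD of 0.29. An effect of the genotype may also contribute (adjusted p = 0.775 with an estimated correlation).

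The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. As the real split gave 0 genes, all 10 splits give at least as many by construction, and this count bears on nothing; the highest other count was 3. For gene lists, 6 of the 10 splits gave at least the 16 lists of the real one, and the highest other count was 23. The lowest unadjusted camera p of any list was 8.54e-15 in the real split and ran from 3.06e-20 to 6.07e-10 in the other splits. A list p of this size at the preset correlation therefore does not mark out the genotype split. Without the block, the 6 splits that kept 2 of the 3 numbered pairs together had 165 to 1461 genes at an unadjusted p under 0.05, 4 of them more than the 780 of the real split and 2 fewer. The 3 other splits that part all pairs had 69 to 135, fewer than any of those 6, which points to a structure of the samples by replicate number. Among the 4 splits that part all 3 pairs, the real one had 1842 genes at an unadjusted p under 0.05 with the replicate block, and 1 of the 4 splits, the real one, gave as many; the other 3 had 185 to 364. Those 4 splits are too few for a share under 0.05 as well. The other 3 each exchange the genotypes of 1 pair.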
